A study of Mus musculus with 5 samples.

How the data were processed

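Bulk RNA sequencing of CD11b-positive brain cells gave 1 library per mouse, and each mouse was taken as a separate animal from its title. The titles and the extraction protocol name CD11b-positive cells, whereas the description of the libraries speaks of brain tissue without the cerebellum. How the cells were isolated is not given in the sources used here. Groups were assigned from the titles: 2 libraries of 5xFAD mice (replicates 1 and 3) and 3 libraries of 5xFAD mice with the Cd5l transgene (replicates 1, 2 and 3).

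The values used were the counts per Ensembl gene as deposited by the authors, in 1 table of 56748 genes with 1 column per library. They were whole numbers, with no normalisation. The genome build was GRCm39 (mm39), per the submitters' processing notes, and coordinates are given as the authors' table lists them. The aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here, so reads of a gene and of an antisense or overlapping gene may not have been told apart. Counts of near-identical genes, among them the alpha-globin genes, the Pira family, Gm3411, the class I MHC genes, the interferon-inducible GTPases and ribosomal protein genes with many pseudogenes, depend on how shared reads were assigned. Columns were matched to libraries by name. The name of 1 column, that of Cd5l-transgenic replicate 3, had the letter pairs of its library name in the opposite order, and it was matched by its letters and number. No per-sample column was left unused.

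Library totals ran from 30798377 to 34794617 counts, so that a single count was worth about 0.0287 to 0.0325 CPM and the limit set by 3 counts about 0.0862 to 0.0974 CPM. Such limits cover counting error only. The 20 most abundant genes took between 11.3% and 12.95% of the counts.

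Genes were filtered with filterByExpr of edgeR 4.0.16 by group, which kept 17724 genes. Counts were scaled with TMM factors (0.952 to 1.02) and tested with the edgeR quasi-likelihood test with robust settings, under R 4.3.3. The design held the genotype alone, differences were coded as Cd5l-transgenic minus 5xFAD, and p-values were adjusted by Benjamini-Hochberg over the tested genes with a threshold of 0.05. The biological coefficient of variation was 0.26. CPM values are scaled by TMM. Standard errors of edgeR were derived from the fold change and the F statistic.

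The groups, tests, alternatives, 38 tested gene lists and the rule for named genes were fixed before the data were examined. The rule named Cd5l first. Then came genes past the threshold whose transgenic libraries all lay on one side of both 5xFAD libraries, with a mean of at least 5 CPM and a symbol that is not a provisional one, up to 12 per direction by size of change. As none passed, each direction was filled to 6 genes by smallest unadjusted p. Each list named up to 2 members by smallest unadjusted p, since no member passed over all genes. Further genes are named where another test called them, and values of some genes under this rule are not reported here. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, two-sided, with adjustment over the 38 lists. Medians of lists are differences of mean log2 CPM on that scale, while values of single genes are edgeR log2 fold changes. Camera compares a list with all other genes, whereas fry tests whether the genes of a list move on balance, or in either direction in its mixed form. A list member counted as measured if it passed the filter under its symbol. Genes in more than 1 list, such as Trem2, Itgax, Stab1 and Chil3, were counted in each.

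The scripts were tested on simulated counts for 17724 genes with the means, dispersions and library sizes of these samples, 3 libraries against 2. For that comparison edgeR recovered 71 of 100 genes changed 2-fold and 91 of 100 changed 8-fold, with 21 unchanged genes called, and DESeq2 recovered 84 and 95, with 74 unchanged genes called. Genes were simulated independently, without differences between libraries that many genes share. These shares are therefore not the recovery to expect in the real data. Camera called a list of 20 independent genes shifted by 0.5 on the log2 scale, and 7 of 200 unshifted lists fell below the unadjusted threshold of 0.05. The unshifted lists also held independent genes, so they do not show the error rate for lists whose genes move together. In the real data the lists that passed with the preset correlation had estimated correlations from 0.0574 to 0.955.

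Alternatives were size factors of DESeq2 and upper-quartile factors in the edgeR test, the Wald test of DESeq2 1.42.0, limma-voom with sample weights, the older quasi-likelihood method, no low-count filter, a filter of 5 CPM in 2 samples, the replicate number as a block, and leaving out each library in turn. For lists they were camera with an estimated correlation and fry. Where a library left out leaves 1 mouse in 5xFAD, that mouse is assumed to vary like those of the other group. An alternative that leaves out 5xFAD replicate 3 and Cd5l-transgenic replicate 2 together was added after the data were seen. Wild-type mice and any 5xFAD replicate 2 were not analysed here. No batch, date or sex is named in the labels.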

Results

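RNA was sequenced from CD11b-positive brain cells of 5 mice that were 7 months old. CD11b is a surface integrin of microglia and other myeloid cells, and the cerebellum had been removed before the cells were taken. Of the 5 libraries, 2 came from 5xFAD mice (replicates 1 and 3), a transgenic line that develops amyloid plaques. The other 3 libraries (replicates 1, 2 and 3) came from 5xFAD mice that also carried mouse Cd5l under the human PDGF-B promoter, called Cd5l-transgenic below. Wild-type mice, which the design of the series also names, were not analysed here. The libraries held 31007840 and 34794617 counts for 5xFAD replicates 1 and 3, and 30798377, 31333716 and 32874316 counts for Cd5l-transgenic replicates 1, 2 and 3. Every pair of libraries differed by far more than sampling noise, with a chi-square per degree of freedom between 20.9 and 59.6, so all 5 were kept as separate samples. The comparison asked how forced expression of CD5L, a scavenger-receptor-family protein secreted by macrophages, went with gene expression in these cells of 5xFAD mice.

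Cd5l itself (ENSMUSG00000015854, chromosome 3, 87265188 to 87278380, GRCm39) was nearly absent from the 5xFAD libraries and abundant in the Cd5l-transgenic ones. It had 45 and 9 counts in 5xFAD replicates 1 and 3, against 7230, 10680 and 6438 counts in Cd5l-transgenic replicates 1, 2 and 3. The mean was 0.889 ± 0.899 CPM (SD, n = 2) in 5xFAD and 254 ± 72.4 CPM (SD, n = 3) with the transgene, a ratio of means of 286, and the lowest transgenic library exceeded the highest 5xFAD library 128-fold. The log2 fold change of Cd5l was 8.23 with a standard error of 0.60. In the edgeR quasi-likelihood test its unadjusted p of 2.53e-05 was the smallest of all genes, and its adjusted p was 0.448, so it did not pass the threshold there. Without 5xFAD replicate 1 the log2 fold change was 9.95 (adjusted p = 0.0525), and without 5xFAD replicate 3 it was 7.38 (adjusted p = 0.311). In the DESeq2 Wald test the log2 fold change was 8.19 and the adjusted p 6.30e-19. Counts of the transgene and of the endogenous gene fall on the same gene and were not separated. By mean CPM, Cd5l ranked 632 among the 17724 tested genes in the transgenic libraries. The 6 nearest measured genes on chromosome 3 (Kirrel, Gm10705, Fcrls, Fcrl1, Etv3 and Arhgef11) had a median log2 fold change of -0.0515.

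Beyond Cd5l, the tests called few genes as different between the genotypes. Of 17724 tested genes, edgeR called 0 higher and 0 lower. As it did not call Cd5l either, with a ratio of means of 286, these counts do not show that other genes were unchanged. At an unadjusted p under 0.05 there were 202 higher and 265 lower genes, 467 together, where 886 would be expected by chance alone. DESeq2 called 12 genes higher (Cd5l, Myh11, Hba-a1, Pira1, Tagln, Mylk, Acta2, Crispld2, Pde3a, Tpm2, Gm3411 and Gbp4) and 3 lower (Igfbp5, Cxcr4 and Armc2). On the simulated counts DESeq2 called 74 unchanged genes beside 84 and 95 changed ones. There edgeR called 21 unchanged genes beside 71 and 91 changed ones. Both are more than a threshold of 0.05 allows, so calls of either test here and below may include false ones. In 15.9% of genes all transgenic libraries lay on one side of both 5xFAD libraries, against 20% expected by chance for groups of 2 and 3. The first principal component (43.1% of the variance) did not separate the genotypes. On the second (30.8%) all transgenic libraries lay below both 5xFAD libraries, with the nearest scores at -0.884 and -0.0280. Without 5xFAD replicate 1, edgeR called 10 genes lower and 0 higher: Cfap44, Dnah10, Ak7, Ecrg4, Cfap69, Cfap46, Dnah12, Dnah11, Dnah5 and Inava. The only 5xFAD library in that fit was replicate 3, which held the most choroid plexus and ependymal marker RNA (2854 CPM, against 270.1 to 547.1 CPM in the other 4 libraries). With 5xFAD replicate 3 and Cd5l-transgenic replicate 2 left out together, the libraries highest in choroid plexus and oligodendrocyte markers, edgeR called 13 higher and 28 lower, with 1 library of 5xFAD against 2.

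Among genes with a mean of at least 5 CPM and no overlap between the genotypes, those with the smallest unadjusted p in the higher direction after Cd5l were Myh11, Tpm2, Tagln, Pde3a, Mylk and Aoc3. Other genes had larger fold changes with more spread between mice, and those of the gene lists are given with their list. Myh11, the smooth muscle myosin heavy chain (ENSMUSG00000018830, chromosome 16, 14012399 to 14109236), went from 39.4 ± 2.14 CPM (SD, n = 2) in 5xFAD to 87.3 ± 18.4 CPM (SD, n = 3), a log2 fold change of 1.15 with a standard error of 0.18. Tagln, which encodes the actin-binding protein transgelin (chromosome 9, 45840917 to 45847356), had means of 14.8 and 29.5 CPM and a log2 fold change of 1.00 (SE 0.20). Mylk, the kinase of the myosin light chain (chromosome 16, 34565580 to 34822790), had a log2 fold change of 0.95 (SE 0.20), and Tpm2, a tropomyosin (chromosome 4, 43514711 to 43523765), one of 0.90 (SE 0.18). Pde3a, a cyclic nucleotide phosphodiesterase of vascular smooth muscle (chromosome 6, 141194995 to 141453174), stood at 1.05 (SE 0.22), and Aoc3, the vascular adhesion protein and amine oxidase (chromosome 11, 101221431 to 101232764), at 0.98 (SE 0.22). As the rule required, each of these 6 genes was higher in 3 of 3 transgenic libraries than in either 5xFAD library. None passed in edgeR (adjusted p = 0.995 each). All but Aoc3 passed in DESeq2, with adjusted p of 1.45e-05 for Myh11, 0.0166 for Tagln, 0.0170 for Mylk, 0.0318 for Pde3a and 0.0320 for Tpm2. For 5 of the 6 the highest value was in Cd5l-transgenic replicate 2, which also held the most oligodendrocyte and endothelial marker RNA.

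Igfbp5, which encodes a binding protein of insulin-like growth factors (ENSMUSG00000026185, chromosome 1, 72897091 to 72914043), had the smallest unadjusted p among the genes lower with the transgene by the same rule, while others had larger fold changes. It stood at 52.9 ± 4.25 CPM (SD, n = 2) in 5xFAD and 24.3 ± 3.49 CPM (SD, n = 3) in the transgenic libraries, a log2 fold change of -1.12 with a standard error of 0.14. Cxcr4, the receptor of the chemokine CXCL12 (chromosome 1, 128515936 to 128520030), had means of 82.5 and 51.1 CPM and a log2 fold change of -0.69 (SE 0.13). Armc2, a gene needed for the axoneme of motile cilia and flagella (chromosome 10, 41790986 to 41894438), had a log2 fold change of -0.87 (SE 0.16). Wdr6, a WD-repeat protein gene (chromosome 9, 108449510 to 108455938), showed the tightest values, 47.3 ± 1.05 CPM (SD, n = 2) against 37.0 ± 0.405 CPM (SD, n = 3), for a log2 fold change of -0.35 (SE 0.07). Wipf3 (chromosome 6, 54406588 to 54480753) had a log2 fold change of -1.15 (SE 0.26), and Prkaa2, a catalytic subunit of AMP-activated protein kinase (chromosome 4, 104887071 to 104967087), one of -0.66 (SE 0.15). As the rule required, these 6 genes were lower in 3 of 3 transgenic libraries, and none passed in edgeR (adjusted p = 0.995 each). In DESeq2 Igfbp5 (adjusted p = 1.18e-06), Cxcr4 (0.0251) and Armc2 (0.0471) passed.

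**Figure D1:**
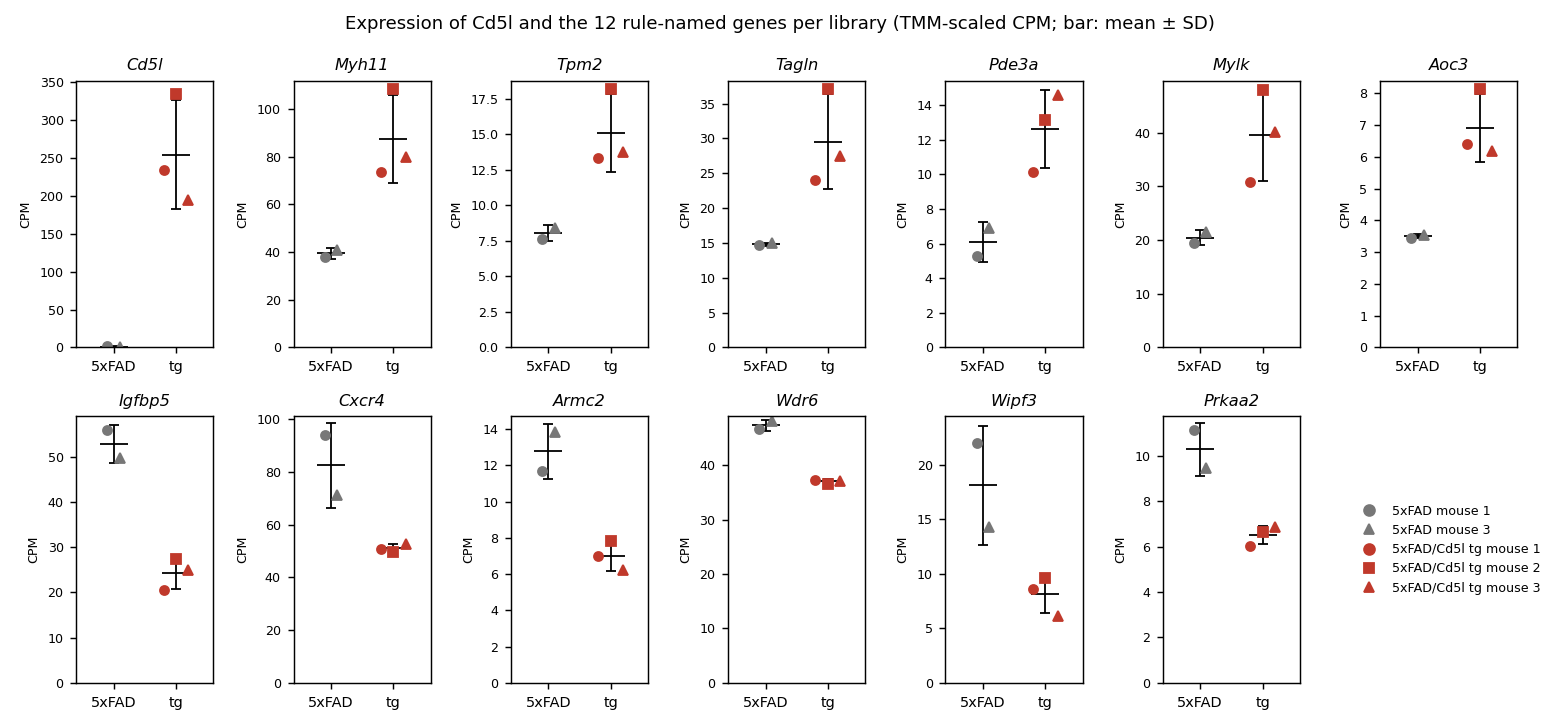
Normalised expression in CPM (vertical axes, from 0) of Cd5l and the 12 named genes in each library, with grey points for 5xFAD mice, red points for Cd5l-transgenic mice (tg), and bars for the mean ± SD. Cd5l lies at 0.254 and 1.525 CPM in 5xFAD and between 194.8 and 334.9 CPM with the transgene. In every panel the points of the genotypes do not overlap, as the rule required of the 12 named genes.

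Gene lists were then compared as groups. Of 38 lists, 9 lay higher and 4 lower with the transgene in the camera test with a preset correlation between genes (adjusted p under 0.05), and 0 passed when the correlation was estimated from the data (lowest adjusted p = 0.665). No member of any list passed the gene-level test over all genes. Adjusted over the list alone, 5 members passed in the erythroid list, 3 in the mural and fibroblast list and 1 in the lipid droplet and fatty acid oxidation list, all by edgeR, and 0 in the others. For each list the median log2 difference over its measured members is given. The values of single members often rested on 1 mouse: of the 73 members named by the rule, 49 had a log2 fold change that shrank by more than 1.5 times without some library, 8 of them to the opposite sign.

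Microglial identity genes did not pass the test, and genes of the plaque-associated state were lower with the transgene in a way that rested on 1 mouse. The 19 homeostatic genes, among them Siglech and Csf1r (log2 fold changes 0.22 and 0.13), had a median of 0.03 (camera adjusted p = 0.202), and without Cd5l-transgenic replicate 2 one of 0.12 (adjusted p = 0.0213). Genes of disease-associated microglia, a state found around plaques, are commonly divided in stages, of which the later depends on Trem2. Of the 8 measured stage 1 genes 7 lay below 0, with a median of -0.11 (adjusted p = 0.238), including Timp2 (-0.22) and Lyz2 (-0.16). Their sum was 58900 CPM in 5xFAD replicate 1, against 38680 CPM in 5xFAD replicate 3 and 46220, 46510 and 38640 CPM with the transgene. Without 5xFAD replicate 1 Timp2 stood at 0.013 and Lyz2 at 0.045, and without 5xFAD replicate 3 the stage 1 median was -0.33 (adjusted p = 6.71e-04). Of the 19 stage 2 genes 18 lay below 0, with a median of -0.24 (adjusted p = 0.00200, and adjusted p = 0.901 with an estimated correlation). Itgax, the integrin CD11c, stood at 1503 and 833.7 CPM in 5xFAD replicates 1 and 3 and at 776.9, 750.2 and 735.7 CPM in the transgenic libraries (log2 fold change -0.63, SE 0.24). Spp1, osteopontin, stood at 2766 and 603.2 CPM in 5xFAD and 744.3, 586.2 and 461.3 CPM with the transgene (log2 fold change -1.50, SE 0.62). Without 5xFAD replicate 1 the values were -0.14 for Itgax and -0.013 for Spp1. The summed stage 2 genes reached 24770 CPM in 5xFAD replicate 1, against 14690 CPM in 5xFAD replicate 3 and 15970, 15320 and 14670 CPM in the transgenic libraries. Without 5xFAD replicate 1 the stage 2 median was 0.07 (adjusted p = 0.178), without 5xFAD replicate 3 it was -0.48, and without Cd5l-transgenic replicate 3 it was -0.18 (adjusted p = 0.0559).

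Genes of uptake and degradation, the functions named in the title of the series, showed no list past the test. The 22 measured phagocytic and scavenger receptor genes had a median of -0.04 (camera adjusted p = 0.978), with the beta-glucan receptor Clec7a at a log2 fold change of -0.28 (SE 0.16), or -0.087 without 5xFAD replicate 1, and the scavenger receptor Stab1 at 0.21 (SE 0.13). Of the 29 lysosomal genes 28 lay below 0, with a median of -0.05 (adjusted p = 0.0665). Atp6v0d2, a subunit of the lysosomal proton pump, stood at 65.6 and 20.85 CPM in 5xFAD and between 14.96 and 17.72 CPM with the transgene (log2 fold change -1.43, or -0.39 without 5xFAD replicate 1), and the calcium channel Mcoln1 had a log2 fold change of -0.20 (SE 0.07). The summed lysosomal genes stood at 70890 CPM in 5xFAD replicate 1 and 57140 CPM in 5xFAD replicate 3, with the transgenic libraries between them at 61780, 60880 and 59240 CPM. Without 5xFAD replicate 3 the lysosomal median was -0.22 (adjusted p = 2.06e-07), a value set by 5xFAD replicate 1 alone. The 19 autophagy genes had a median of -0.06 (adjusted p = 0.202), with Optn at -0.37 and Atg16l1 at -0.17. The 12 measured complement genes had a median of 0.10 (adjusted p = 0.137), with C4b at 0.62 (SE 0.25), and without 5xFAD replicate 1 the median was 0.24 (adjusted p = 0.0372). The 23 mouse counterparts of Alzheimer risk genes had a median of 0.01 (adjusted p = 0.595). Among them Clu stood at -0.78 (SE 0.61) and Trem2 at -0.21 (SE 0.18), and each sign rested on 1 mouse: Clu was at 0.52 without 5xFAD replicate 3, and Trem2 at 0.11 without 5xFAD replicate 1.

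Interferon-response genes were higher with the transgene, and cytokine genes were lower in 2 of the 3 transgenic mice. Of the 23 interferon-response genes 21 lay above 0, with a median of 0.25 (camera adjusted p = 1.91e-07, and adjusted p = 0.665 with an estimated correlation), and 12 were higher in every transgenic library than in either 5xFAD library. The antiviral GTPase Mx1 stood at 30.1 and 33.4 CPM in 5xFAD and at 37.4, 37.3 and 38.8 CPM with the transgene (log2 fold change 0.25, SE 0.08), and the membrane protein gene Ifitm3 had a log2 fold change of 0.30 (SE 0.11). The list passed without any 1 library, with medians from 0.18 to 0.31. Markers of other cell types moved with it: the median centred levels of the endothelial, monocyte and erythroid lists were also higher in every transgenic library than in either 5xFAD library. The 24 inflammatory cytokine and NF-kB target genes had a median of -0.31 (adjusted p = 0.0208, and adjusted p = 0.901 with an estimated correlation), with the chemokine Cxcl2 at -0.44 (SE 0.15) and the cytokine Osm at -0.41 (SE 0.14). That list passed with Cd5l-transgenic replicate 3 left out (median -0.46) and with none of the other 4 libraries left out (medians -0.24 and -0.34 without 5xFAD replicates 1 and 3, -0.26 and -0.05 without transgenic replicates 1 and 2). The summed cytokine genes stood at 5988 and 5393 CPM in 5xFAD, at 3869 and 3576 CPM in transgenic replicates 1 and 2, and at 5746 CPM in transgenic replicate 3, within the 5xFAD range. The immediate early and dissociation list, which shares 2 genes with this list (Ccl3 and Ccl4), moved with it, at 17970 and 16470 CPM in transgenic replicates 1 and 2 and 25040 CPM in replicate 3, against 24920 and 24320 CPM in 5xFAD. Antigen presentation did not pass as a group. The 12 MHC class I genes had a median of 0.02 (adjusted p = 0.505), with the peptide transporter Tap1 at 0.24 and the proteasome subunit Psmb9 at 0.15, and without transgenic replicate 2 the median was 0.08 (adjusted p = 0.0199). The 7 MHC class II genes had a median of -0.10 (adjusted p = 0.950) where the test leaned upward, with their activator Ciita at 0.91 (SE 0.56) and Cd74 at -0.18 (SE 0.34), which was 0.057 without transgenic replicate 2. The 6 measured alternative activation genes had a median of 0.08 (adjusted p = 0.30), with Chil3 at 1.02 (SE 0.39) and Cd163 at 0.22 (SE 0.28), and without transgenic replicate 2 the median was 0.43 (adjusted p = 0.00870).

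Lists of lipid and energy metabolism did not pass the test. The 23 cholesterol biosynthesis genes had a median of -0.04 (camera adjusted p = 0.595), with Mvd at 0.25. That list had opposite signs without either 5xFAD library, 0.15 without replicate 1 (adjusted p = 0.0197) and -0.23 without replicate 3 (adjusted p = 1.00e-03). The 14 fatty acid synthesis genes had a median of 0.04 (adjusted p = 0.595), with Elovl5 at 0.16 and Fads2 at -0.61 (0.27 without 5xFAD replicate 3), and the 11 targets of the sterol-sensing LXR receptors one of -0.03 (mean 0.01, adjusted p = 0.950), with Smpdl3a at -0.23 and Nr1h3 at 0.52. The 21 measured lipid droplet and fatty acid oxidation genes had a median of -0.02 (adjusted p = 0.558). In that list Cidea, a lipid droplet protein gene, passed over the list alone (edgeR adjusted p = 0.00951) at very low levels, 0.373 and 0.621 CPM in 5xFAD and 0 to 0.0314 CPM with the transgene, and Dgat2 stood at -0.88 (SE 0.39), or -0.19 without 5xFAD replicate 3. The 17 glycolysis and hypoxia genes had a median of -0.06 (adjusted p = 0.588), with Hif1a at -0.19 (0.014 without 5xFAD replicate 1) and Slc2a1 at 0.28 (0.023 without transgenic replicate 2). The 30 measured nuclear genes of oxidative phosphorylation had a median of -0.04 (adjusted p = 0.559), with Cox7b at -0.22 and Ndufs6 at 0.23, and the 13 mitochondrially encoded genes one of 0.06 (adjusted p = 0.661), with mt-Nd3 at 0.46 (0.066 without transgenic replicate 2) and mt-Nd4l at -0.34 (0.042 without 5xFAD replicate 3). Without 5xFAD replicate 3 the mitochondrially encoded genes had a median of 0.30 (adjusted p = 0.0441).

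Among genes of cell stress and growth, immediate early genes were lower in 2 of the 3 transgenic mice. Ribosomal protein genes had a slightly higher median, the sign of which rested on 5xFAD replicate 3. Immediate early genes such as Fosb and Ier3 respond within minutes to stimulation, and also to the handling that cell isolation needs. Of 28 such genes 25 lay below 0, with a median of -0.32 (camera adjusted p = 1.18e-05, and adjusted p = 0.828 with an estimated correlation). Fosb stood at 648.3 and 782.7 CPM in 5xFAD and at 384.9, 304.7 and 586.9 CPM with the transgene (log2 fold change -0.75, SE 0.29), and Ier3 had a log2 fold change of -0.49 (SE 0.15). The summed list was 24920 and 24320 CPM in 5xFAD, 17970 and 16470 CPM in transgenic replicates 1 and 2, and 25040 CPM in transgenic replicate 3, which is above both 5xFAD mice. Without 5xFAD replicate 3 the median was -0.37 (adjusted p = 0.0698), and without transgenic replicates 2 and 3 in turn it was -0.17 and -0.49, past the test in both. Of 52 ribosomal protein genes 47 lay above 0, with a median of 0.08 (camera adjusted p = 6.83e-04, and adjusted p = 0.901 with an estimated correlation). Among them were Rps27 at 0.33 (SE 0.12) and Rps24 at 0.22 (SE 0.12), or 0.068 without 5xFAD replicate 3. The summed ribosomal genes stood at 19800 and 16060 CPM in 5xFAD and at 19870, 18950 and 17510 CPM with the transgene. Of the 3 transgenic libraries, 2 thus lay within the 5xFAD range. The ribosomal median was -0.07 without 5xFAD replicate 3 (adjusted p = 0.0566) and 0.04 without transgenic replicate 1 (adjusted p = 0.148), and it was 0.24 without 5xFAD replicate 1 and 0.15 without transgenic replicate 3. The 12 genes of the unfolded protein and integrated stress response had a median of -0.01 (adjusted p = 0.170) where the test leaned upward, as it did for the phagocytic receptors, with Asns at 0.66 and Chac1 at 1.10. The 27 cell cycle genes had a median of -0.07 (adjusted p = 0.30), with Stmn1 at 0.54 (0.26 without transgenic replicate 2) and Kif11 at -0.50 (-0.17 without 5xFAD replicate 3), and without transgenic replicate 3 the median was -0.23 (adjusted p = 1.98e-04).

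**Figure D2:**
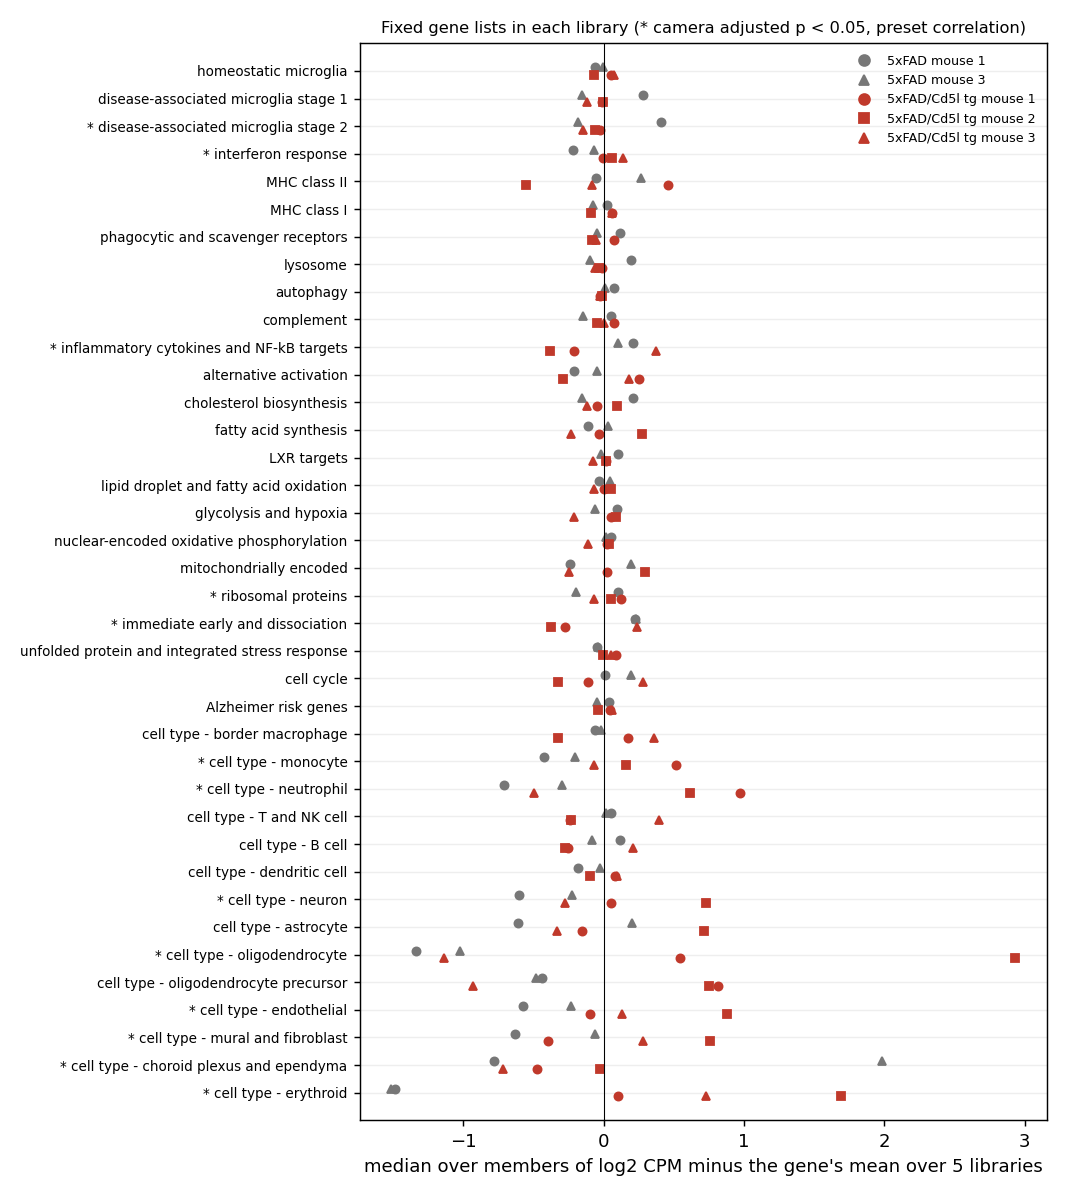
The 38 gene lists in each library, as the median over a list's members of the log2 CPM minus the gene's mean over the 5 libraries (horizontal axis, log2), with grey points for 5xFAD mice, red points for Cd5l-transgenic mice, and an asterisk for a camera adjusted p under 0.05 with a preset correlation. The erythroid and interferon lists have every transgenic library above both 5xFAD libraries, whereas 5xFAD mouse 1 stands apart in the stage 2 list at 0.4048 and 5xFAD mouse 3 in the choroid plexus list at 1.979.

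Among markers of leukocytes, border macrophages and red blood cells, the monocyte, neutrophil and erythroid lists passed the test. Of the 9 measured monocyte genes 8 lay above 0, with a median of 0.65 (camera adjusted p = 1.35e-04, and adjusted p = 0.665 with an estimated correlation), with Plac8 at 0.98 (SE 0.35) and Chil3 again at 1.02. The monocyte list passed without any 1 library, with medians of 0.27 without transgenic replicate 1 and 0.84 without transgenic replicate 3. The summed monocyte genes stood at 168.5 and 229.7 CPM in 5xFAD and at 226.3, 342.6 and 201.9 CPM with the transgene, so that 2 of the 3 transgenic libraries lay within the 5xFAD range. Of the 13 measured neutrophil genes 11 lay above 0, with a median of 0.89 (adjusted p = 1.98e-04, and adjusted p = 0.828 with an estimated correlation), with the granule protein genes Camp at 1.42 (SE 0.39) and Ngp at 1.07 (SE 0.38). Their median was 0.58 without 5xFAD replicate 1 (adjusted p = 0.0540), 0.51 without transgenic replicate 1 and 1.36 without transgenic replicate 3. The summed neutrophil genes hardly differed, at 1143 and 1130 CPM in 5xFAD and 1042, 1169 and 1147 CPM with the transgene, and 2 of the 13 were higher in every transgenic library. The median centred level of the list was -0.50 in transgenic replicate 3, below the -0.29 of 5xFAD replicate 3. All 5 measured erythroid genes were higher in every transgenic library, with a median of 2.33 (adjusted p = 9.71e-09, and adjusted p = 0.665 with an estimated correlation). Their sum was 2.41 and 1.47 CPM in 5xFAD and 7.40, 20.8 and 8.53 CPM with the transgene. The alpha-globin genes Hba-a1 and Hba-a2 are near-identical copies whose reads cannot be assigned with certainty. Hba-a2 stood at 0.0678 and 0.0847 CPM in 5xFAD, no more than 3 counts, and between 0.485 and 0.941 CPM with the transgene. Hba-a1 had a log2 fold change of 3.43 (SE 0.84) and passed in DESeq2 (adjusted p = 1.40e-04). The 13 border macrophage genes had a median of 0.18 (adjusted p = 0.0747), with Dab2 (0.070 without 5xFAD replicate 3) and Stab1 both at 0.21, and without transgenic replicate 2 the median was 0.32 (adjusted p = 2.11e-05). The 13 measured T and NK cell genes had a median of 0.08 and a mean of -0.11 (adjusted p = 0.890, leaning upward), with Klrd1 at 0.52 and Lck at -0.55. The 7 measured B cell genes had a median of -0.07 (adjusted p = 0.950), with Ebf1 at 0.88 and Cd79b at 0.39, and the 7 measured dendritic cell genes one of 0.27 (adjusted p = 0.30), with Zbtb46 at 0.27 and Clec9a at 0.51.

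Markers of neural cells differed widely between single mice. All 14 oligodendrocyte genes lay above 0, with a median of 1.98 (camera adjusted p = 2.16e-06, and adjusted p = 0.828 with an estimated correlation), and their sum was 2438 and 2090 CPM in 5xFAD against 3047, 6844 and 2250 CPM in the transgenic libraries. The myelin genes Mobp and Mal had log2 fold changes of 3.76 (SE 1.35) and 2.73 (SE 1.13). Without transgenic replicate 2 the oligodendrocyte median was 0.83 (adjusted p = 1.68e-04), and the list passed without any 1 library. The 6 measured oligodendrocyte precursor genes had a median of 0.46 (adjusted p = 0.122), with Olig1 at 3.20 (SE 1.45) and Olig2 at 3.76 (SE 1.74), and without transgenic replicate 3 the median was 0.84 (adjusted p = 0.00210). The 16 measured neuronal genes had a median of 0.49 (adjusted p = 0.00599, and adjusted p = 0.846 with an estimated correlation), with the synaptic gene Snap25 at 2.12 (SE 0.75) and Eno2 at -0.75 (SE 0.28). Their sum was low, between 34.7 and 68.6 CPM. Their median was 0.41 without 5xFAD replicate 1 (adjusted p = 0.272), 0.10 without transgenic replicate 2 (adjusted p = 0.369) and 0.78 without 5xFAD replicate 3, and it was -0.17 among the members kept by a stricter expression filter (adjusted p = 0.764). The 14 astrocyte genes had a median of 0.16 (adjusted p = 0.202), with Slc1a2 at 0.82 and Aldoc at 0.87, and without 5xFAD replicate 3 the median was 0.66 (adjusted p = 0.00109). All 10 choroid plexus and ependymal genes lay below 0, with a median of -1.04 (adjusted p = 0.00815, and adjusted p = 0.901 with an estimated correlation). Ttr, the transthyretin gene, stood at 390.6 CPM in 5xFAD replicate 1 and 2478 CPM in 5xFAD replicate 3, against 204.3, 442.2 and 288.1 CPM with the transgene, and Folr1 had a log2 fold change of -1.70 (SE 0.70), or -0.051 without 5xFAD replicate 3. The choroid plexus median was 0.41 without 5xFAD replicate 3 (adjusted p = 0.0608), -2.37 without 5xFAD replicate 1 and -0.80 without transgenic replicate 3 (adjusted p = 0.103).

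Vessel markers were higher with the transgene. All 12 endothelial genes lay above 0, with a median of 0.68 (camera adjusted p = 1.17e-06, and adjusted p = 0.828 with an estimated correlation), and 8 were higher in every transgenic library. Vwf, the von Willebrand factor gene, had a log2 fold change of 1.19 (SE 0.38) and Pecam1 one of 0.80 (SE 0.30). The endothelial sum was 718.3 and 708.5 CPM in 5xFAD and 839.4, 1530 and 844.7 CPM with the transgene, and without transgenic replicate 2 the median was 0.33 (adjusted p = 7.64e-05). Of the 12 mural and fibroblast genes 11 lay above 0, with a median of 0.49 (adjusted p = 1.35e-04, and adjusted p = 0.828 with an estimated correlation). Myh11 and Tagln led this list with the values given above. Its sum was 186.4 and 269.3 CPM in 5xFAD and 256.6, 463.3 and 351.5 CPM with the transgene. The mural median was 0.21 without 5xFAD replicate 1 (adjusted p = 0.209), 0.27 without transgenic replicate 2, 0.81 without 5xFAD replicate 3 and 0.82 without transgenic replicate 1, and the list passed in the last 3 of these.

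**Figure D3:**
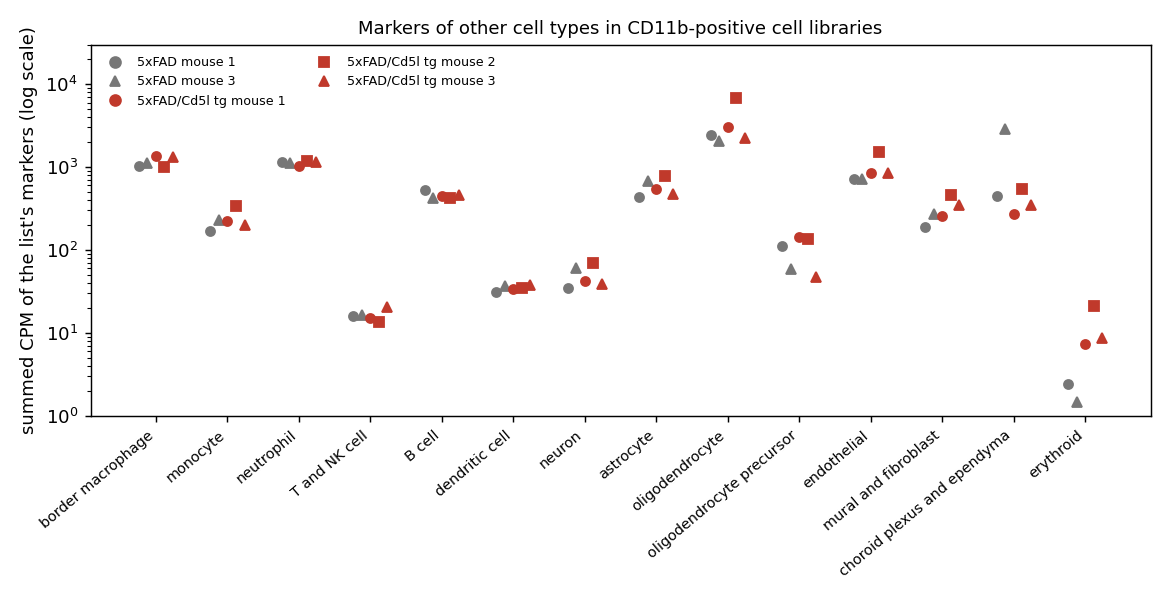
Summed CPM of the marker genes of 14 other cell types (vertical axis, log scale) in each library, with grey points for 5xFAD mice and red points for Cd5l-transgenic mice. Oligodendrocyte markers peak at 6844 CPM in Cd5l-transgenic mouse 2, choroid plexus markers at 2854 CPM in 5xFAD mouse 3, and erythroid markers stay below 21 CPM in every library.

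Genes related to the transgenes and to sex were read as values. App stood at 454 and 462 CPM in 5xFAD and 465, 725 and 462 CPM with the transgene. Pdgfb, the mouse gene whose human counterpart gave the promoter, stood at 283 and 240 CPM in 5xFAD and at 210, 223 and 296 CPM in the transgenic libraries. Xist, the RNA of the inactive X chromosome, lay between 894 and 1338 CPM in every library. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had 0 counts in all 5, which allows at most 0.0862 to 0.0974 CPM per library. By these genes all 5 libraries read as female.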

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

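Leaving out 5xFAD replicate 3 and Cd5l-transgenic replicate 2 together was chosen after the results were seen, and the other alternatives were planned. Under other scaling factors, limma-voom, the older quasi-likelihood method and both other filters, 0 genes were called higher and 0 lower. The DESeq2 Wald test called 12 higher and 3 lower and gave Cd5l a log2 fold change of 8.19. Leaving out each library in turn gave 0 higher and between 0 and 10 lower genes. Leaving out the pair gave 13 higher and 28 lower genes and a Cd5l value of 7.14 (adjusted p = 5.96e-06). The edgeR adjusted p of Cd5l otherwise ran from 0.0525 without 5xFAD replicate 1 to 1.00, with log2 fold changes up to 9.95. In the fit without the pair, the spread between mice came from transgenic replicates 1 and 3 alone. Their chi-square per degree of freedom, 20.9, was the lowest of all pairs of libraries. The cause of the differences between settings was not tested. Other scalings moved the median of all genes by less than 0.1.

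For the lists, camera with an estimated correlation called 0 higher and 0 lower, fry in its directional form 0 and 0 and in its mixed form 0 and 0. Leaving out each library in turn gave 8 to 12 higher and 2 to 4 lower lists, and the interferon, monocyte, oligodendrocyte, endothelial and erythroid lists passed each time. Of the 25 lists that did not pass, 12 passed without some library. With each library left out in turn, stage 2 genes of disease-associated microglia ran from -0.48 to 0.074, cholesterol genes from -0.23 to 0.15, ribosomal protein genes from -0.073 to 0.24 and choroid plexus genes from -2.37 to 0.41. Without the pair of libraries the ribosomal median was -0.067 and the choroid plexus median 0.18. Under the filter of 5 CPM in 2 samples the neuronal median was -0.17, where fewer members were kept.

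With the replicate number as a block, 0 genes were called, Cd5l stood at 8.02 (adjusted p = 1.00), and 12 lists were higher and 4 lower, 11 of the 13 calls being shared. The calls lost were those of the cytokine list (adjusted p = 0.721) and the neuronal list (adjusted p = 0.219). Samples of the same number are different animals, and their deviations from the group means correlated at 0.129 for number 1 and -0.24 for number 3, so the numbers were not taken to pair them. At these depths 1 count is worth about 0.03 CPM, so values under about 0.1 CPM rest on 3 counts or fewer.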

Other observations

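The tests of vessel fragments, of the share of CD11b-positive cells, of neuronal RNA, of promoter activity and of the weight of 5xFAD replicate 1, and the lists of contractile, pericyte and GTPase genes, were chosen after the results were seen. The test of genes next to Cd5l and the counts over other splits were set beforehand.

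Interferon-inducible GTPases, which act against intracellular pathogens downstream of interferon gamma, were not among the lists fixed at the start. All 16 measured members lay above 0, with a median log2 difference of 0.70 and quartiles of 0.44 and 1.04, and 7 were higher in every transgenic library than in either 5xFAD library. Gbp4 stood at 8.34 and 11.7 CPM in 5xFAD and at 24.1, 16.6 and 31.8 CPM with the transgene (log2 fold change 1.26, SE 0.32), Gbp5 had a log2 fold change of 0.72 (SE 0.23) and Gbp2 one of 1.29 (SE 0.50). The summed list was 312.8 and 380.1 CPM in 5xFAD and 541, 368.7 and 629.5 CPM in transgenic replicates 1, 2 and 3, so replicate 2 lay within the 5xFAD range. Border macrophage genes moved alike, with sums of 1017 and 1113 CPM in 5xFAD and 1345, 1013 and 1324 CPM in transgenic replicates 1, 2 and 3, and so did Ciita, at 4.81 and 7.45 CPM against 15.6, 4.61 and 14.6 CPM. The GTPase median ran from 0.48 without 5xFAD replicate 1 to 0.93 without 5xFAD replicate 3.

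Pira1, an activating receptor gene of the paired immunoglobulin-like family, stood at 0.847 and 0.480 CPM in 5xFAD and 4.23, 2.67 and 4.42 CPM with the transgene, a log2 fold change of 2.53 (SE 0.43, edgeR adjusted p = 0.995), and passed in DESeq2. Its relatives Pira2 and Pira12 had log2 fold changes of 0.04 (SE 0.81) and 1.00 (SE 0.65). Crispld2, a secreted glycoprotein gene, stood at 1.69 and 2.12 CPM against 4.85, 6.08 and 4.12 CPM. These genes were singled out after their values were seen.

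Cd5l was abundant in the transgenic libraries of CD11b-positive cells although the PDGF-B promoter is best known for driving transgenes in neurons. A change of the wider region around the endogenous gene is argued against by the 6 measured genes nearest to it, whose median log2 fold change was -0.0515. A rise of endogenous Cd5l alone would leave these genes unmoved. It stays open, as counts of the endogenous gene were not told apart from those of the transgene. Activity of the promoter within the cells themselves is a candidate explanation, since endogenous Pdgfb reached at least 209.6 CPM in every library. Cd5l did not follow Pdgfb, though 3 libraries cannot decide this. In transgenic replicates 1, 2 and 3 Pdgfb stood at 210, 223 and 296 CPM, and Cd5l at 234, 335 and 195 CPM. RNA carried over from neurons stays open, as the ratio of Cd5l to the summed neuronal markers differed only 1.13-fold between its highest and lowest value in the transgenic libraries (5.54, 4.88 and 5.01), which 3 libraries cannot set apart from chance. Single markers differed in how closely they followed Cd5l. In transgenic replicates 1, 2 and 3 Camk2a stood at 11.2, 16 and 10.4 CPM, close to proportion. Nrgn stood at 1.68, 3.73 and 0.514 CPM, out of proportion. Cd5l exceeded the neuronal marker Snap25 139-, 117- and 268-fold in the same libraries. Carry-over alone would need neurons to hold Cd5l RNA in about such an excess over Snap25. How much Cd5l neurons of these mice hold was not measured.

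Contractile smooth muscle genes, of which 3 are also in the mural list, lay higher together with the transgene, with 14 of 14 measured members above 0, a median log2 difference of 0.95, and 12 members higher in every transgenic library. The list was chosen after members such as Myh11 were seen to be higher, so these counts partly restate that. A lower share of CD11b-positive cells, which would raise all other cell types alike, is not decided by the astrocyte genes. Their upper quartile of 0.301 lay below the lower quartile of the contractile genes, 0.819, and did so without any 1 library. That lower quartile is high in part by the choice of the list. Oligodendrocyte and endothelial medians were also higher, at 1.98 and 0.68, while the choroid plexus median was lower, at -1.04. Vessel fragments carried into the libraries are a candidate explanation, as pericyte genes, of which 4 are also in the mural list, had a median of 0.489. That value rests on single mice, at 0.17 without transgenic replicate 2 and 0.19 without 5xFAD replicate 1, while the contractile median stayed between 0.80 and 1.10. A difference in the vessels of transgenic mice was not tested and stays open.

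The lower stage 2 genes of disease-associated microglia followed 5xFAD replicate 1. Without that mouse the median log2 difference was 0.0738, so the pattern may reflect a high level in 1 animal, and whether 5xFAD mice differ in plaque load was not tested. An effect of the transgene stays open, since 2 mice cannot show which level is usual for 5xFAD.

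The 5 libraries can be divided into groups of 2 and 3 in 10 ways, too few for a share under 0.05. The genotypes gave 467 genes at an unadjusted p under 0.05, and the highest of the other splits gave 1733. As many genes came from 7 of the 10 splits, the real one included. The split with 1733 set 5xFAD replicate 3 and transgenic replicate 2 against the rest. The same 2 libraries lay at 31.9 and 49.4 on the first principal component, against -49.2, -3.16 and -28.8 for the others, a structure of the samples other than genotype, but apart on the second, at 55.6 and -37.5. Their summed astrocyte markers were the highest, at 683.9 and 777.6 CPM, against 437.5 to 539 CPM in the others. So were their neuronal markers, at 59.99 and 68.59 CPM, against 34.7 to 42.18 CPM. Their oligodendrocyte markers were unlike, at 2090 and 6844 CPM. What sets these libraries off from the others was not tested. The genotypes gave 13 lists and the highest other split 19, with as many from 8 of the 10 splits.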
